A study of Canis lupus familiaris with 6 samples.

How the data were processed

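RNA was measured in 6 libraries from MDCK type II cells, a dog kidney epithelial line: 3 libraries from wild-type cells (WT) and 3 from cells in which E-cadherin had been knocked out (KO). Per the labels' protocols, poly-A RNA from 250 ng of total RNA was made into stranded libraries with dUTP in the second strand and read as 75-base pairs on a NextSeq 500. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or how many KO clones they represent, so every p-value measures only the spread between these libraries, which may be technical. The labels also differ on cell density: the series text gives confluent dishes and the growth protocol 70 to 80% confluency. Density was therefore not known, while genotype was checked by the level of the targeted transcript.

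Per the submitters' processing notes, FastQC, STAR 2.5.2b, Picard 2.8.1, featureCounts and DESeq2 1.14.1 were used; the genome build and annotation are not given in the sources used here. The authors deposited 1 table of 12851 Ensembl dog genes, with a normalized count for each of the 6 libraries, a signal that is not a whole number of reads. In each library, 71.3 to 81.0% of values under 12 lay within 0.1 of a whole multiple of a common step of 0.859 to 1.14, so whole reads could not be recovered for nearly all genes and no count test was run. Taking that step as about 1 read, the deposited totals of 18281549 to 19386796 normalized counts correspond to about 16928973 to 22569029 reads per library. Per the file headers, the table also holds the authors' mean of normalized counts, log2 fold change of KO over WT with its standard error, a score (the fold change over its error), a p-value and an adjusted p-value. The ratio of the mean of the 6 libraries to the deposited mean reached 1.5 and no more, with 60 genes within 1e-06 of that value. That is what a mean over 9 libraries gives, so the authors' fit included further libraries, which are not analysed here.

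The design fixed before the data were examined assumed raw counts, with a fallback for normalized values; the fallback was used. Values were transformed to log2(value + 1), and 12349 genes with a mean of at least 10 over the 6 libraries were kept. Each gene was tested with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes moderation with trend and robust options from statmod 1.5.0, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. The step was tested on simulated data for KO against WT with 12298 genes: 87% of 100 genes changed 1.5-fold and 100% of 100 genes changed 3-fold were recovered, with 12 false calls among 199. Changes were planted only in genes with a mean well over the filter of 10, and in few genes, whereas 48.1% of real tested genes were called. Recovery of lower genes and false calls at that share were not tested. Replicates were compared before averaging. Pearson correlations of log2 values were 0.987 to 0.991 within a group and 0.934 to 0.940 between groups, and no pair within a group agreed within sampling noise, with chi-square values per gene of 3.40 to 14.3.

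Gene groups were 37 lists fixed before the data were examined. The 32 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and tested again with an estimated correlation and with fry. The genes named were fixed by rule: CDH1, the 10 largest rises and 10 largest falls among called genes with a symbol, no overlap between groups and a mean of at least 100 in the higher group, up to 4 called members per list with the smallest adjusted p, and 25 key junction and mesenchymal genes. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here. Where a symbol stood on several rows, the row with the highest mean was used. Reads shared between near-identical genes could not be assessed from this table.

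Neighbouring genes were compared by the gene order of the dog assembly UU_Cfam_GSD_1.0, used only for which genes lie beside each other. Of 10003 distinct symbols tested, 9788 (97.9%) had a place; 2246 tested rows without a symbol were not placed. The 8533 placed genes with a mean of at least 100 were cut into runs of at least 15 genes by recursive circular binary segmentation (fold changes held within 1.5 on the log2 scale, 1000 permutations per split, split p of at most 0.001) in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Runs with a median shift of at least 0.25 were called blocks. This step was added after the data were seen; with shuffled gene order it found 0 blocks, and it recovered 60 of 60 planted genes shifted 1.5-fold. Alternatives tried were rescaling of libraries, limma without trend and robust options, other filters and pseudocounts, a replicate block, a minimum fold of 1.5, leaving out each library, leaving out block genes and the authors' own calls.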

Results

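The data were 6 poly-A RNA libraries from MDCK type II cells, a canine kidney epithelial line widely used to study cell junctions and polarity. Of these, 3 came from wild-type cells (WT) and 3 from cells in which the gene for the adhesion receptor E-cadherin had been knocked out (KO). Each library held 18281549 to 19386796 normalized counts, or about 16928973 to 22569029 reads. The libraries of a group resembled each other more closely (Pearson r across genes of 0.987 to 0.991) than those of different groups (0.934 to 0.940). Values below are normalized counts, given as mean ± SD with n = 3 libraries per group, and log2 fold changes are fitted on log2(value + 1). Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

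The comparison asks how the transcriptome of these epithelial cells differs once E-cadherin function is lost. Transcript from the targeted gene, CDH1 (ENSCAFG00845010704), was present at 38542, 39643 and 39370 normalized counts in the 3 WT libraries and at 1115, 1120 and 1237 in the 3 KO libraries. The KO mean was 2.95% of the WT mean, a log2 fold change of -5.08 (SE 0.047, adjusted p = 1.33e-16), and the authors' deposited table gives -5.08 (SE 0.050). Across the transcriptome, 2920 of 12349 tested genes were higher in KO and 3021 were lower, while 6408 did not pass. Desmosome, tight junction, epithelial identity and stress response genes fell as groups and inflammatory genes rose as a group by camera with a preset correlation; with an estimated correlation none of these lists passed (lowest adjusted p = 0.231). Most called changes were small: 659 genes were at least 2-fold higher and 411 at least 2-fold lower. The 3 WT and 3 KO values did not overlap for 5812 of the called genes and for 6967 of all tested genes, where chance gives 10%. The authors' deposited table called 2701 of the same tested genes higher and 2854 lower at the same threshold, and 5508 genes were called in both in the same direction and 0 in opposite directions.

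Adherens junction genes changed in both directions. Of 18 tested catenins, nectins and adaptors, 5 rose, 8 fell and 5 did not pass (5 and 9 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.377). CTNNA1, which links the cadherin complex to actin, fell from 28408 ± 537 to 22478 ± 431 (log2 fold change -0.34, SE 0.034), and JUP, plakoglobin, fell by 0.57 on the log2 scale. CTNNB1, beta-catenin, was 1.09-fold higher (adjusted p = 0.0149), a call lost without WT replicate 1 (adjusted p = 0.0529), without KO replicate 1 (adjusted p = 0.0662) and in limma without trend and robust options (adjusted p = 0.0758). CTNND1, p120-catenin, had a log2 fold change of -0.13 (adjusted p = 0.0505) and passed without WT replicate 3 (adjusted p = 0.0320), without KO replicate 3 (adjusted p = 0.0138) and with a minimum mean of 50 (adjusted p = 0.0488). CTNND2, delta-catenin, which lies in a block of neighbouring genes that fell and was chosen after its values were seen, fell from 63.0, 59.2 and 52.7 in WT to 0, 0 and 0.839 in KO. The adaptors SORBS2 and LMO7 fell 4.52-fold and 3.56-fold, and NECTIN1 and ARVCF rose 2.16-fold and 1.89-fold. Among 11 tested members of the cadherin superfamily, 5 rose and 3 fell, the targeted CDH1 among the latter (camera adjusted p = 0.721). The kidney cadherin CDH6 fell from 15274 ± 178 to 9970 ± 535, PCDH1 fell 1.54-fold, and CDH16 rose from 36.8 ± 4.26 to 147 ± 18.9. CDH3, P-cadherin, was at 509 ± 30.9 and 471 ± 20.5 (adjusted p = 0.242), and CDH2, N-cadherin, lay under the filter on low values.

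**Figure D1:**
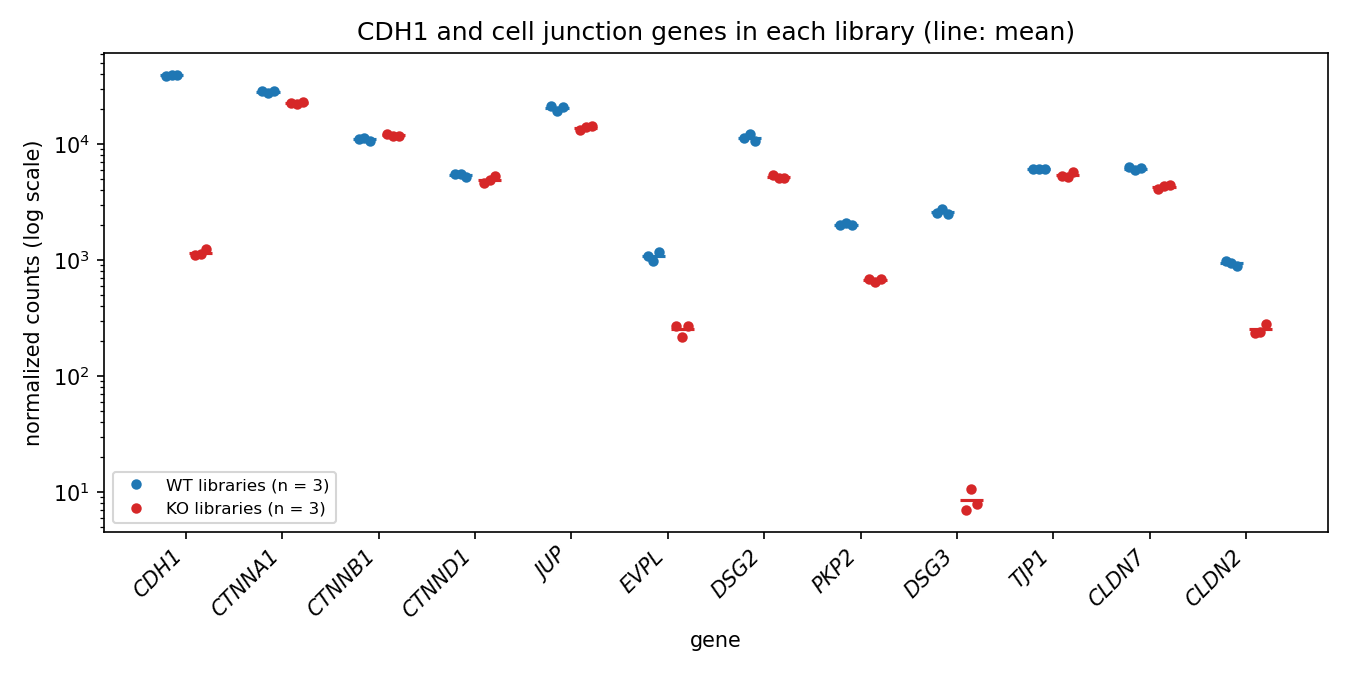
Normalized counts (log axis) of 12 junction genes in each WT library (blue) and KO library (red), with a line at each group's mean. CDH1 is at 38542 to 39643 in WT and at 1115 to 1237 in KO, and DSG3 falls from 2608 to 8.50 on average, while CTNNB1 and CTNND1 lie close together in both groups.

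Desmosome genes had the lowest median of the 32 lists tested with camera (-1.13 on the log2 scale): 7 of 9 tested members fell, 0 rose and 2 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.000123; adjusted p = 0.231 with an estimated correlation). The desmosomal cadherin DSG3 fell from 2608 ± 123 to 8.50 ± 1.87, and DSG2 fell 2.19-fold. The plaque protein PKP2 fell 3.01-fold and the cornified envelope protein EVPL 4.28-fold. In the tight junction list, 14 of 22 tested members fell, 3 rose and 5 did not pass (15 and 3 adjusted over the list alone; camera adjusted p = 0.0111, and adjusted p = 0.480 with an estimated correlation). The pore-forming claudin CLDN2 fell 3.71-fold, CGNL1 2.79-fold and CLDN7 1.43-fold, while JAM3 rose from 2.39, 0 and 0 in the WT libraries to 130, 148 and 137 in the KO libraries (log2 fold change 6.53, and 7.12 without WT replicate 1). The median of this list was -0.34 and its mean -0.15. TJP1, which encodes ZO-1, fell by 0.17 on the log2 scale (adjusted p = 0.00544). OCLN, occludin, fell by 0.18 (adjusted p = 0.0147), a call lost without WT replicate 1 (adjusted p = 0.0663) and without KO replicate 3 (adjusted p = 0.0682). Of 8 tested gap junction genes, 2 rose and 4 fell (adjusted p = 0.721), with GJB1 up 7.14-fold, GJC1 up 4.21-fold and GJB5 down 1.72-fold. Polarity genes were divided, with 5 of 21 higher and 4 lower (adjusted p = 0.786).

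Epithelial identity genes fell as a list, with 15 of 27 tested members lower, 3 higher and 9 not passing, also adjusted over the list alone (median -0.20; camera adjusted p = 0.0110, and adjusted p = 0.480 with an estimated correlation). EHF, an epithelial ETS factor, fell 1.98-fold, the splicing regulator ESRP1 by 0.68 on the log2 scale and MAL2 1.72-fold, whereas EPCAM was at 8518 ± 398 in WT and 8120 ± 417 in KO (adjusted p = 0.263). KRT15 fell from 36238 ± 2963 to 18208 ± 753 and KRT80 rose 1.30-fold, while KRT18 had a log2 fold change of 0.00 (SE 0.057, adjusted p = 0.982). Transcription factors of epithelial-mesenchymal transition did not move together: 3 of 8 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.721). ZEB1 rose from 22.4 ± 4.18 to 87.4 ± 11.8 and SNAI1 from 127 ± 3.60 to 248 ± 16.3, the latter lying in a block of neighbouring genes that rose, while SNAI2 fell from 238 ± 4.57 to 177 ± 10.7. Of 9 mesenchymal and fibroblast markers, 5 rose and 1 fell (adjusted p = 0.267), with FN1 up 1.62-fold, COL5A2 up by 0.68 on the log2 scale and S100A4 down 1.74-fold. VIM, vimentin, was abundant in both groups at 89974 ± 5515 and 94046 ± 3148 (adjusted p = 0.232), and passed only without WT replicate 3 (adjusted p = 0.0350). ZEB2, TWIST1, KRT8 and MKI67 were not analysed here.

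Inflammatory genes rose. In the list of NF-kappa-B and inflammatory genes, 17 of 21 tested members rose, 1 fell and 3 did not pass, over all genes and adjusted over the list alone (median 0.69; camera adjusted p = 2.03e-05, and adjusted p = 0.231 with an estimated correlation). The chemokine CCL2 rose from 373 ± 16.7 to 5046 ± 275, the apoptosis inhibitor BIRC3 3.27-fold and the growth factor CSF1 6.60-fold. CXCL8 rose from 3.89 ± 3.01 to 199 ± 16.8 and LCN2, lipocalin 2, from 0, 5.36 and 0.860 to 167, 174 and 202. Without WT replicate 2 the log2 fold change of CXCL8 went from 5.55 to 6.02 and that of LCN2 from 6.31 to 7.05. The exception was PTGS2, cyclooxygenase 2, which fell from 3417 ± 118 to 20.8 ± 1.71. Interferon-stimulated genes did not follow: 5 of 25 rose and 12 fell (6 and 12 adjusted over the list alone; adjusted p = 0.267), among them USP18, down 3.49-fold, and ISG15, down 2.58-fold. The unfolded protein and integrated stress response list fell, with 18 of 24 members lower, 2 higher and 4 not passing (19 and 2 adjusted over the list alone; median -0.47; camera adjusted p = 6.19e-05, and adjusted p = 0.480 with an estimated correlation). Asparagine synthetase, ASNS, fell from 16115 ± 326 to 9737 ± 264, the serine pathway enzyme PSAT1 fell 1.54-fold, the amino acid transporter subunit SLC3A2 1.86-fold and CHAC1 2.20-fold.

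**Figure D2:**
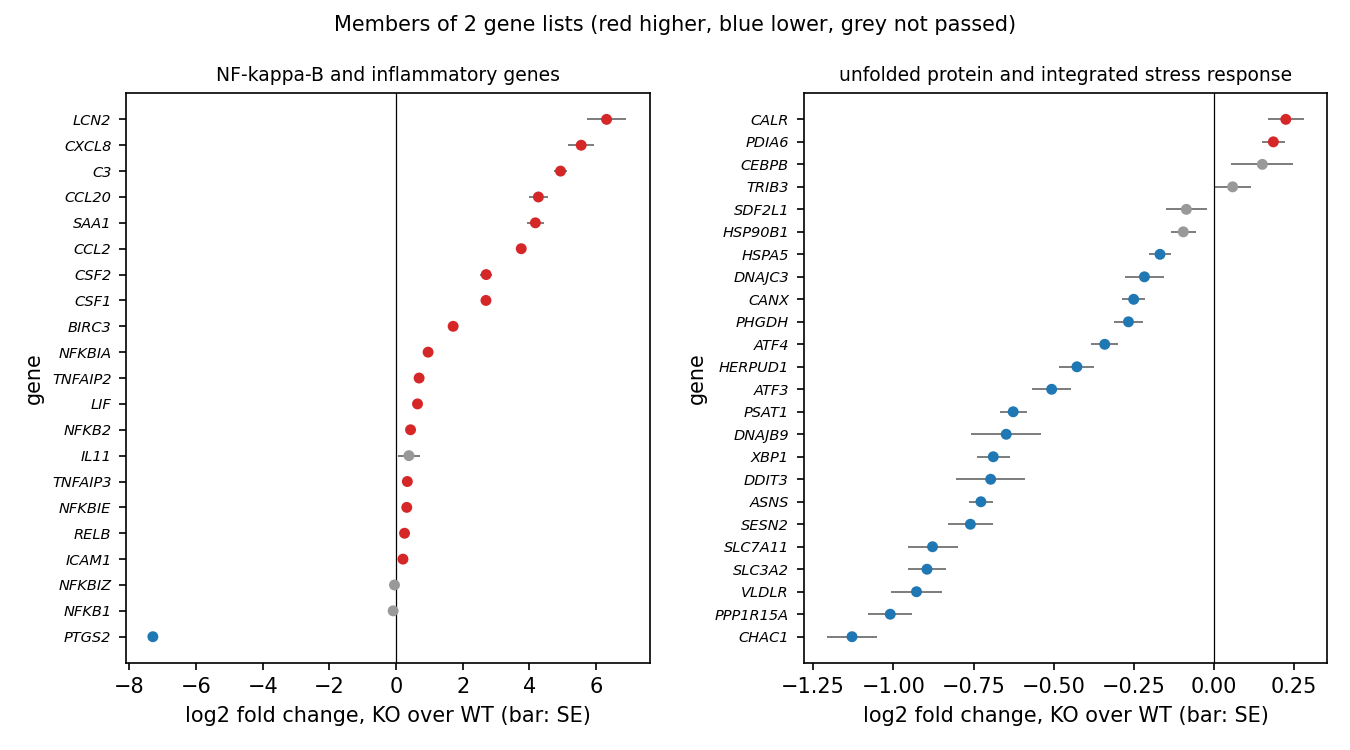
Log2 fold change of KO over WT with its SE for each tested member of the inflammatory list (left, 21 genes) and the stress response list (right, 24 genes), coloured by call. On the left, 17 members are higher and PTGS2 alone is lower. On the right, 18 are lower and 2 higher.

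Matrix and adhesion genes changed in both directions. Of 15 basement membrane genes, 9 rose and 3 fell (adjusted p = 0.267): the collagen IV chains COL4A2 and COL4A1 rose 4.19-fold and 2.81-fold, while the nephronectin gene NPNT fell from 4185 ± 59.5 to 652 ± 17.6 and LAMB3 fell 2.73-fold. Of 19 matrix enzymes and inhibitors, 7 rose and 8 fell (adjusted p = 0.735), with the protease PLAU up 2.86-fold and MMP15 down 6.20-fold. Of 13 integrins, 3 rose and 7 fell (4 and 7 adjusted over the list alone; adjusted p = 0.523), among them ITGB3, down 1.30-fold, and ITGAV, up 1.30-fold. Of 28 focal adhesion adaptors, 12 rose and 7 fell (13 and 8 adjusted over the list alone; adjusted p = 0.447), with SRC, which lies in the same block as SNAI1, up from 2644 ± 148 to 5765 ± 198. Of 27 actomyosin genes, 7 rose and 11 fell (adjusted p = 0.721): the non-muscle myosin gene MYH10 rose 2.19-fold, MYH14 fell 2.21-fold and ACTB rose 1.16-fold. Guidance genes held 16 higher and 8 lower of 31 (16 and 9 adjusted over the list alone; adjusted p = 0.267), with SLIT2, also in a block that rose, up from 1060 ± 51.1 to 4830 ± 167 and PLXND1 up 3.91-fold.

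None of the remaining signalling lists passed camera. Of 22 YAP and TAZ targets, 8 rose and 5 fell (8 and 6 adjusted over the list alone; adjusted p = 0.629). ANKRD1 rose 4.44-fold and CCN1 1.41-fold, CCN2 fell by 0.24 on the log2 scale, and YAP1 itself had a log2 fold change of 0.01 (adjusted p = 0.916). Of 12 Wnt and beta-catenin targets, 7 rose and 2 fell (adjusted p = 0.267), with CCND1 up 1.91-fold, NOTUM 2.79-fold, ZNRF3 2.29-fold and SP5 3.77-fold. Of 18 TGF-beta and BMP targets, 8 rose and 7 fell (adjusted p = 0.629), INHBA rising 3.72-fold and its antagonist FST falling 4.13-fold. Notch genes were 5 higher and 4 lower of 11 (5 and 5 adjusted over the list alone; adjusted p = 0.897), EGFR ligands and receptors 4 and 5 of 16 (adjusted p = 0.731), and immediate early genes 4 and 6 of 19 (adjusted p = 0.442), FOS among them at 2.81-fold lower. Of 35 proliferation genes, 11 rose, 2 fell and 22 did not pass (adjusted p = 0.377). For p53 targets the counts were 5 and 3 of 20 (adjusted p = 0.735), for cholesterol genes 7 and 8 of 23 (8 and 8 adjusted over the list alone; adjusted p = 0.735), for glycolysis and hypoxia genes 8 and 10 of 24 (adjusted p = 0.682), for ribosomal proteins 5 and 5 of 32 (4 and 5 adjusted over the list alone; adjusted p = 0.721) and for the respiratory chain 2 and 4 of 21 (1 and 4 adjusted over the list alone; adjusted p = 0.629). For lists with no count given as adjusted over the list alone, that count was the same. Median and mean differed in sign for the cadherin superfamily (0.31 and -0.05), gap junctions (-0.28 and 0.29), focal adhesion adaptors (0.14 and -0.03), actomyosin genes (-0.07 and 0.06), YAP and TAZ targets (0.10 and -0.19) and Notch genes (-0.14 and 0.05). The camera direction followed the median in these lists except Notch. The mean of the cadherin superfamily includes the targeted CDH1 (log2 fold change -5.08).

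**Figure D3:**
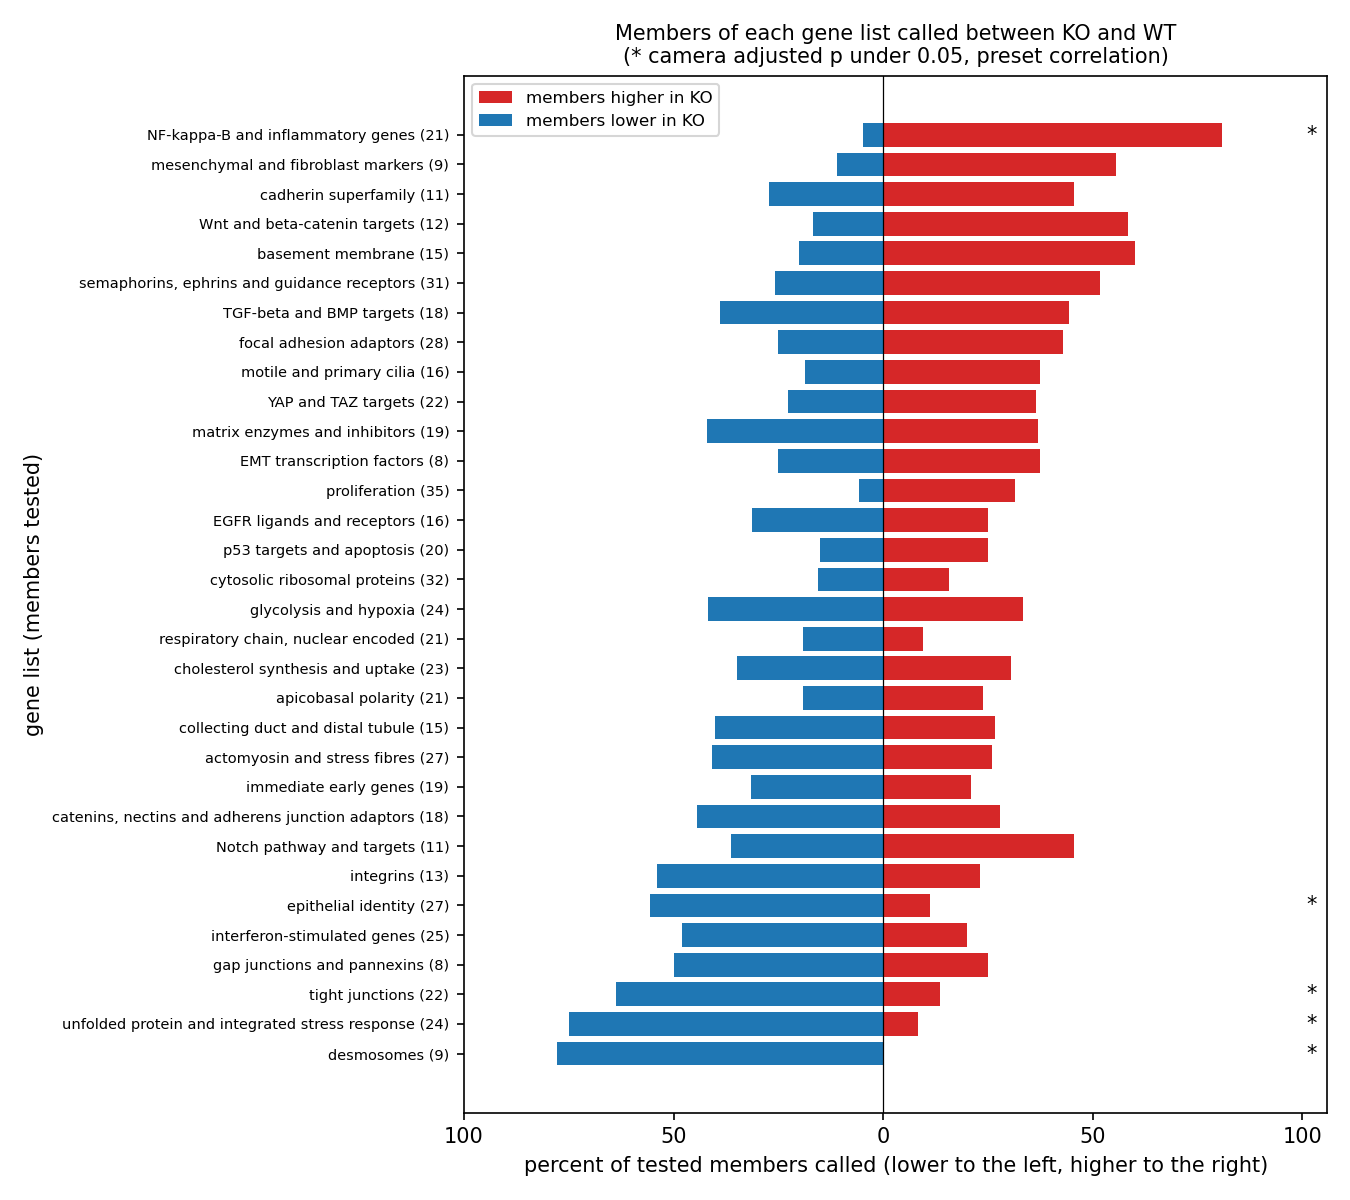
Percent of tested members of each of 32 gene lists called higher (red, right) or lower (blue, left) in KO, ordered by median fold change, with the number tested in brackets. An asterisk marks the 5 lists that passed camera, 1 upward and 4 downward; with an estimated correlation 0 lists passed.

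Kidney segment genes changed in both directions. Of 15 collecting duct and distal tubule genes, 4 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.377). The regulator GATA3 fell 3.31-fold, carbonic anhydrase 2, CA2, from 12986 ± 712 to 5506 ± 156, and TFAP2B from 59.8, 61.9 and 58.1 to a listed 0 in every KO library. Of 16 cilia genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.301), with the ciliogenesis regulators FOXJ1 and RFX2 up 5.49-fold and 10.2-fold and PKHD1 down 3.62-fold. Only 4 proximal tubule genes could be tested, of which MIOX, CUBN and FBP1 fell and SLC22A12 rose. Markers of other cell types were few: the endothelial receptor FLT1, in a block that fell, was 1.84-fold lower, and 3 immune markers rose, among them CD14, 2.37-fold, and CD74, 1.11-fold. No mitochondrially encoded gene was among those tested. The CD74 call was lost in limma without trend and robust options (adjusted p = 0.119) and without WT replicate 2 (adjusted p = 0.0583), KO replicate 2 (adjusted p = 0.0576) or KO replicate 3 (adjusted p = 0.0822).

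The largest single changes were losses. BCHE, butyrylcholinesterase, was at 7704, 8673 and 7418 in WT and at 0.982, 0 and 0 in KO, and the ion channel gene TRPA1 at 3541, 4188 and 3456 in WT and listed at 0 in every KO library. S100A16, PDE1A, POU3F3, LSAMP, FSTL1 and IRX1 had WT means of 602, 524, 445, 364, 337 and 275 and were also listed at 0 in the 3 KO libraries, and ATP10A was at 425, 433 and 407 in WT and 1.01, 0.927 and 0 in KO. In all, 43 genes had a WT mean of at least 30 and no KO library above 3, against 10 genes in the opposite direction. For those 10, every KO library also had to lie above 3, a condition that left out 1 gene. The 10 largest rises under the naming rule were, besides JAM3, LCN2 and CXCL8 above, those of TM4SF18, from 6.96 ± 1.01 to 1361 ± 78.2, COL23A1, from 1.37, 0 and 1.03 to 150, 141 and 143, GAS7 (70.0-fold), LBP (68.6-fold), TNFRSF1B (38.2-fold), DTX4 and ZNF215. DTX4 rose from 15.7, 6.30 and 3.48 to 551, 545 and 616, with a log2 fold change of 6.13 and of 6.64 without WT replicate 1. ZNF215 rose from 0.840, 2.99 and 0.633 to 139, 147 and 134, with a log2 fold change of 5.94 and of 6.34 without WT replicate 2. The log2 fold change of COL23A1 was 6.43, and 6.67 without WT replicate 1.

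Some changes followed gene position. In 5 blocks of neighbouring genes, 3 higher and 2 lower in KO, fold changes were shifted together. The largest ran from SMOX to UBE2V1: 140 of its genes entered the search, with a median of 1.94-fold higher in KO, and 157 of the 160 tested genes within it were called higher. SNAI1, SRC, TPX2, UBE2C and BCL2L1 lie in this block. SLIT2 lies in a block of 23 genes with a median 1.68-fold higher, and TGFBI and IRF1 in a block of 29 genes with a median 1.33-fold higher. FLT1 lies in a block of 23 genes with a median log2 fold change of -0.43, and BCHE and IRX1 lie in a block of 97 genes with a median of -0.34, in which 71 of 112 tested genes were called lower and 17 higher, DNAH5 among the latter (6.06-fold). The block of 97 genes is a whole sequence of the assembly. No split was made in it, so it qualified by its median alone and not by a split p. The higher blocks held 8.42% of the placed genes called higher and 83 of the 538 placed genes called at least 2-fold higher.

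**Figure D4:**
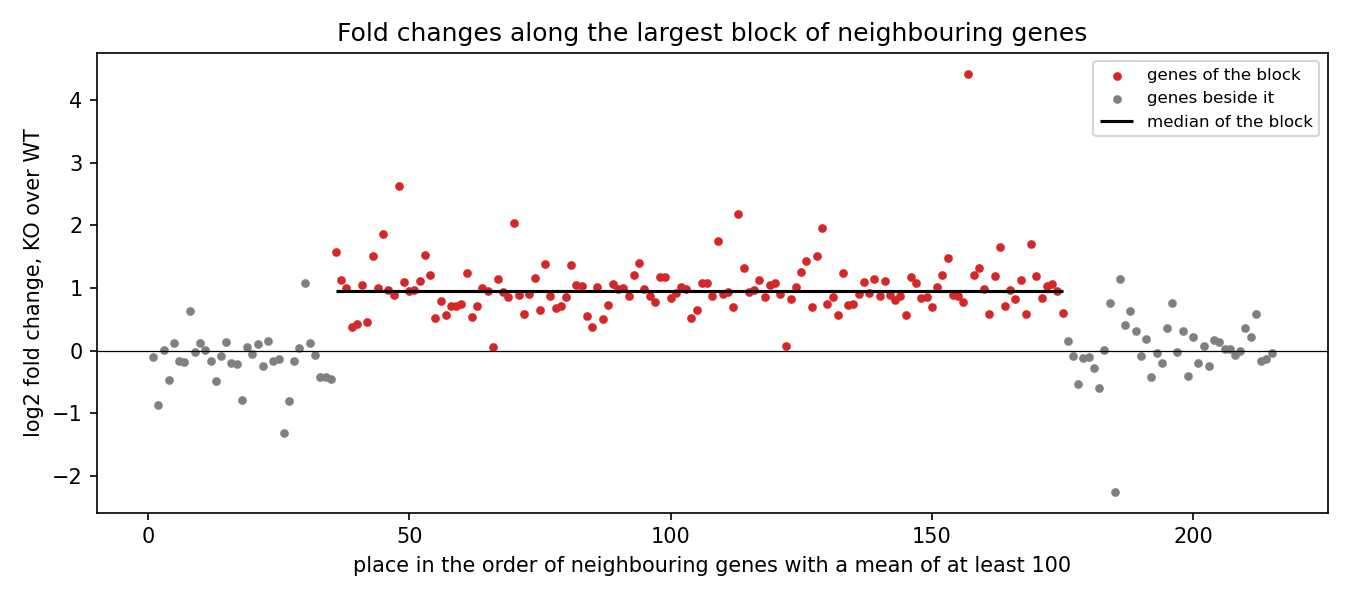
Log2 fold change of KO over WT (vertical axis) for genes in their order along the assembly (horizontal axis), for the 140 genes of the block from SMOX to UBE2V1 (red; line, median 0.96) and 75 genes beside it (grey; median -0.06).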

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

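Signals appeared in a deposited column, seen only after the data were examined, that the comparison did not use, the authors' mean of normalized counts. Of the genes in the table, 48 were listed at 0 in all 6 libraries and still had a deposited mean above 0, from 4.66 to 562. For FLNC, filamin C, the deposited mean was 329.26, while its highest value in the 6 libraries was 0.909. The ratio of the 6-library mean to the deposited mean never exceeded 1.5, which is what a mean over 9 libraries gives. The further libraries are not analysed here, and which cells they came from is not known. No biological explanation was tested.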

How the results depend on the processing

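The CDH1 change kept its call under every alternative run. The counts of genes higher in KO and genes lower in KO stayed within 1.5 times of the reported ones except under a minimum fold. Tested against a fold of 1.5, 688 genes were higher and 446 lower, since that test asks for more. Leaving out each library in turn gave 2493 to 2918 genes higher, 2559 to 2998 lower, CDH1 from -5.13 to -5.06 and 5 lists each time; 84.0 to 91.3% of the called genes were called again. With the replicate block, 3000 genes were higher, 3118 lower and 5 lists passed, the CDH1 change was -5.08, CTNND1 passed (adjusted p = 0.0495), and the numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.03, -0.19 and 0.03. Rescaling moved the median log2 fold change by 0.0129 and the share of calls that were higher from 49.1 to 51.7%. The lists depended on the test: 5 passed camera with a preset correlation, 0 with an estimated correlation and 25 by fry, which does not compare a list with other genes. By fry the cadherin superfamily (median 0.31), gap junctions (-0.28) and YAP and TAZ targets (0.10) passed in the direction opposite to camera. In each of them the direction by fry was that of the mean (-0.05, 0.29 and -0.19), and the cadherin mean includes the targeted CDH1. The cause was not tested further. Leaving out block genes and using the authors' deposited calls were chosen after seeing the data; they gave 2682 and 2911, and 2701 and 2854, genes higher and lower. Over all alternatives and named genes, 2297 results kept their call, 13 lost it and 5 gained it, with none reversed. The alternatives written for raw counts (relative log expression factors, a second count model and voom) were not run because the values are not counts.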

Other observations

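All tests in this part were chosen after the result they bear on was seen, except 2 whose bounds were written first: the inflammatory list without block genes, and the aminoacyl-tRNA synthetases. The real grouping of the 6 libraries called 5941 genes and the highest of the other 9 splits called 2; as many genes were called in 1 of 10 splits, the real one, and 10 splits are too few for a share under 0.05.

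The following genes were chosen after their values were seen, and no list of them was tested. CYP1A1, a classic aryl hydrocarbon receptor target, fell from 420 ± 51.6 to 5.66 ± 0.923, while AHRR, the receptor's repressor, rose from 7.61 ± 3.82 to 151 ± 20.6 and CYP1B1 rose 1.95-fold. ALDH1A1, a retinaldehyde dehydrogenase, fell from 5112 ± 263 to 70.0 ± 6.29. The imprinted gene SNRPN fell from 16167 ± 470 to 3061 ± 135. SPP1, osteopontin, rose from 201400 ± 3239 to 323442 ± 5585.

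A hypothesis for the fall of the stress response list is a lower amino acid response, which acts through ATF4. The list also holds unfolded protein response genes, and the tests given here do not bear on the fall of those. The hypothesis was tested on cytosolic aminoacyl-tRNA synthetases, a list written before it was tested, although 1 member, GARS1, had been seen. Of 19 tested members, 12 fell, 1 rose and 6 did not pass (median -0.21; camera p = 0.000256; p = 0.0894 with an estimated correlation), and without GARS1 the camera p was 0.000675. Of 15 mitochondrial synthetases, which served as a contrast, 1 fell and 3 rose. Their camera p was 0.468. Of 15 amino acid synthesis and import genes, 14 fell (camera p = 3.21e-07; p = 0.0205 with an estimated correlation). Of the 10 that were not in the stress response list, 9 fell, and the camera p of those genes was 6.89e-05. These values go with a lower amino acid response in KO. They cannot tell it from another cause of lower ATF4 activity, such as a lower unfolded protein response, which was not tested. The difference between the cytosolic and mitochondrial lists was not itself tested, and a difference in density or medium between the cultures stays open.

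The blocks of neighbouring genes may reflect a difference in copy number between the lines. Chance order is argued against for the largest block, from SMOX to UBE2V1. There, 0 of 100 shuffled orders gave a running median over 25 genes as large as the real one (1.01, against at most 0.391). Only the largest running median was compared, so these shuffles do not decide the other blocks. In the block from SMOX to UBE2V1, the abundant genes had medians of 1.09, 0.917 and 0.858 at low, middle and high expression. These fell as expression rose but lay within 0.2274 of each other, under the bound of 0.3 that a common shift was taken to need. The 20 genes too low to have been used in finding the block (median 1.4082, against 0.958 for the 140 used) decide nothing, since 6 had a WT mean under 10 and entered through KO. Low genes chosen by WT mean alone (20) or KO mean alone (16) exceeded the 140 by 0.39 and 0.451, which by the rule as first written (a bound of 0.3) counts against a common shift; the rule was changed after those differences were seen, to ask that the 95% bootstrap intervals (0.0842 to 0.816 and 0.218 to 1.00) lie past the bound, and by the changed rule the question is undecided. Copy number was not measured, and an altered clone cannot be separated from E-cadherin loss without independent KO clones.

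The genes near 0 in every KO library were weighed against 2 technical explanations. Lower depth is argued against by a mean depth of KO over WT of 0.965. For the 38 placed genes as a set, a deletion that also removes a placed neighbour's transcript is argued against. Of these, 0 had a neighbour also near 0, and the median of their neighbours' log2 fold changes was -0.154. Single genes stay open: 1 of the 2 neighbours of MIOX fell at least 2-fold, with a median of -3.21 over both. For S100A16, 2 of 2 neighbours (S100A14 and S100A2) fell at least 2-fold, with a median of -1.67. Genes near 0 without a symbol had no place and could not count as neighbours, and a deletion within 1 gene would pass unseen. A regional effect stays open: 7 of the 38 (18.4%) had a neighbour that fell at least 2-fold, against 6.45% of other placed genes (Fisher's exact test, two-sided p = 0.0102), and 3 lay in lower blocks, which hold 1.42% of placed genes. Silencing in the cells from which the KO line was grown, and silencing after E-cadherin loss, both stay open and were not tested.

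The rise of the inflammatory list could come from members lying in shifted blocks, but of its 21 tested members only CSF2 lies in 1 of them. Without block genes the list still passed in the same direction (camera adjusted p = 2.38e-05), an outcome that leaving out 1 member could hardly change. The members outside blocks had a median log2 fold change of 0.67, so the rise was not confined to blocks. With an estimated correlation and all members the camera adjusted p was 0.231. Cell density and the choice of KO clone stay open and were not tested.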
